A study of Arabidopsis thaliana with 8 samples.

How the data were processed

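Total RNA of *Arabidopsis thaliana* (ecotype Wassilevskija, MS medium) was measured on 8 arrays, 4 of WT and 4 of the *atpd* mutant, with the genotype and a replicate number from 1 to 4 taken from the sample titles. The deposited table gives an intensity per probe and array on a linear scale. How the authors made these intensities is not stated in the labels or per the file headers: the background correction, the scaling, and the reason for the values at 0 and the ceiling at 100 are not given in the sources used here. The scale is therefore arbitrary and whether the arrays were normalised before deposit is unknown. The table has no counts or depth. The number of arrays limits the precision.

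Probes were named through the platform annotation supplied with the table. It lists 1562 of the 3439 probes, 692 with a single gene and 870 with several, and the remaining 1877 are unnamed here. Of the 692, 690 matched the reference gene table (assembly TAIR10.1), which was used for names only and not for coordinates, since the files name no build. No gene was named from a probe with several. For the 6 tested loci of photosystems, antenna and Calvin cycle the median brightness lay at the 97.0th percentile of tested probes.

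Values at or below 0 were treated as missing, and a probe was tested with at least 3 values in each genotype, which left 2921 probes. The medians of positive values differed by up to 153% between arrays and the totals by up to 23.2%, over the 5% allowed, so log2 values were quantile-normalised between arrays. Each probe was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are log2 *atpd* minus WT. Intensities given as mean ± SD are the deposited values, while log2 changes and folds come from the normalised ones, so both need not give the same ratio. Probes with at least 3 values in a genotype and at most 1 in the other were counted apart, with no fold.

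Before the data were examined, 18 lists of Arabidopsis loci (264 loci) were written from textbook knowledge. Of these, 15 loci were tested. The label written beside a locus was compared with the reference's symbol and synonyms. It was found for 201 of 222 labelled loci, and for 8 of the 10 labelled loci among the 15 tested. The other 7 tested loci carry only their locus tag as symbol in the reference, which gives no descriptions. For AT1G74470 a synonym names the geranylgeranyl reductase of the list. The identity of the rest was not checked and is as the list was written, and no locus was dropped. Lists with at least 3 tested genes were tested with limma's camera (preset correlation 0.01, an estimated correlation beside it) and with fry, adjusted over the lists. For these set tests only, a missing value was replaced by the mean of its probe in its genotype, and probes of the same gene were averaged. A further 11 lists were put together from probe names after the data, including the intensities of some of the brightest probes, had been seen.

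Genes named in the text follow a rule fixed before the data were examined: ATPD first, then the 10 largest increases and 10 largest decreases among single-gene probes past the threshold whose *atpd* values all lie on the same side of the WT mean, and the 3 members with the smallest p of each list with at least 3 tested genes. Tested members of shorter lists are given as well.

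Alternatives fixed beforehand were the values as deposited, a common median, cyclic loess, other filters and treatments of zeros, a pseudocount, the replicate number as a block, each array left out, an intensity trend with a robust prior, array weights and averaging of probes. Alternatives chosen after seeing the data were array pairs as a random block (duplicateCorrelation, statmod 1.5.0), pair means, the array set as a block, each set alone, removal of probe column medians, leaving out probes at 100 and keeping only probes above 0 on all arrays. Whether replicate numbers pair the samples was checked from deviations from the genotype means. WT and *atpd* arrays of the same number correlated at 0.362, 0.277, 0.289 and 0.276 across probes, all over 0.1. WT and *atpd* arrays of different numbers in the same set correlated at 0.168 to 0.274, below every same-number value. The numbers therefore share a set and may also share a pair. Within a genotype, arrays 1 and 2 and arrays 3 and 4 resembled each other (0.190 and 0.197 in WT, 0.611 and 0.751 in *atpd*), against -0.854 to -0.578 for arrays of different sets. Deviations from a genotype mean sum to 0, which by itself pushes correlations within a genotype below 0.

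The fit was tested on simulated data with the 2921 probes' own levels and spreads and a known set of changed probes, in a single draw per setting. With independent errors, 16.5% of changes of 0.5 log2 were recovered, 55.2% of changes of 1 and 90.5% of changes of 2, and 7 of 109 calls were false. With errors shared within array pairs (correlation 0.688), 108 of 238 calls were false when arrays were treated as independent, and 10 of 95 with pairs as a random block. Of the 2721 unchanged probes, 3.97% and 0.37% were called. The false share among calls depends on how many probes change, so it does not carry over to the real data.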

Results

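RNA abundance was measured on 8 arrays of *Arabidopsis thaliana*, ecotype Wassilevskija, grown on MS (Murashige and Skoog) medium. Per the labels, 4 arrays carried total RNA of wild-type plants (WT) and 4 carried RNA of the *atpd* mutant, which lacks the delta subunit of ATP synthase. This subunit, in the chloroplast enzyme, links the catalytic head to the membrane-embedded part. The series sets the mutant against WT and so asks which transcripts differ when the subunit is missing. Each array gave an intensity for 3439 probes. A single gene was named for 692 probes, several genes for 870 and none for 1877. On the scale of the deposited table, intensities ran from 0 to a ceiling of 100, and between 395 and 430 probes per array were at 0. The number of arrays, 4 per genotype, limits the precision. The labels do not say whether the 4 arrays of a genotype came from separate plants or cultures, so p-values measure only the spread between these arrays, which may be technical.

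The knocked-out gene itself could not be used to check the labels. No probe was named for ATPD alone, and no member of the chloroplast ATP synthase list was tested, so its level is not analysed here.

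Several photosynthesis transcripts were lower in *atpd*. PSAN, a lumenal subunit of photosystem I, fell by 1.49 on the log2 scale (SE 0.23, adjusted p = 0.000707), from a deposited intensity of 13.6 ± 2.01 in WT to 4.29 ± 0.531 in *atpd* (mean ± SD, n = 4 in each). PRK, the phosphoribulokinase of the Calvin cycle, fell by 1.51 (SE 0.12, adjusted p = 2.61e-05), from 3.77 ± 0.408 to 1.59 ± 0.0534. LHB1B2, a chlorophyll a/b protein of the main light-harvesting antenna, fell by 1.14 (SE 0.17, adjusted p = 0.000717), from 62.3 ± 3.70 to 20.2 ± 2.79. Antenna genes of this family are nearly identical in sequence, so the probe cannot be assigned to LHB1B2 alone with certainty. PSAN and PRK stayed past the threshold in every scaling of the arrays that was tried, but the size of the change ranged from -0.90 to -2.82 for PSAN and from -0.87 to -2.41 for PRK. The change of LHB1B2 ranged from -0.37 to -2.80, and after cyclic loess its call was lost (adjusted p = 0.0562). Bright probes shifted as a class too. The median change of the 50 brightest was -0.57 after quantile normalisation, -1.04 as deposited, -2.20 with a common median and -0.003 after cyclic loess. How much of the falls above belongs to that shift was not separated.

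Among the 3 tested members of the photosystem II list, 1 rose, 1 fell and 1 did not pass the test, both over all probes and adjusted over the list alone. PSBW, a small subunit of photosystem II, rose by 2.14 on the log2 scale (SE 0.14, adjusted p = 1.09e-05), from an intensity of 10.1 ± 1.01 to 28.0 ± 3.24 (n = 4 in each). With the arrays shifted to a common median, this difference was 0.30 and not past the threshold (adjusted p = 0.201). PSBY, another small subunit, fell by 0.89 (SE 0.19, adjusted p = 0.00419). That call was lost after cyclic loess (adjusted p = 0.155) and with the means of array pairs (adjusted p = 0.104). PSB27, a factor in photosystem II assembly and repair, differed by 0.17 (SE 0.19, adjusted p = 0.470). Of the chlorophyll synthesis list, 2 members were tested and neither passed. The difference was 0.046 (SE 0.20, adjusted p = 0.867) for AT1G74470, the geranylgeranyl reductase that makes the phytol tail, and -0.018 (SE 0.17, adjusted p = 0.938) for CHLM, the magnesium protoporphyrin methyltransferase. With the values as deposited, PSB27 was higher by 1.11 (adjusted p = 0.000446) and CHLM by 1.01 (adjusted p = 0.000607), close to the shift of all probes on that scale, and with a common median AT1G74470 was at -0.90 (adjusted p = 0.0116).

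**Figure D1:**
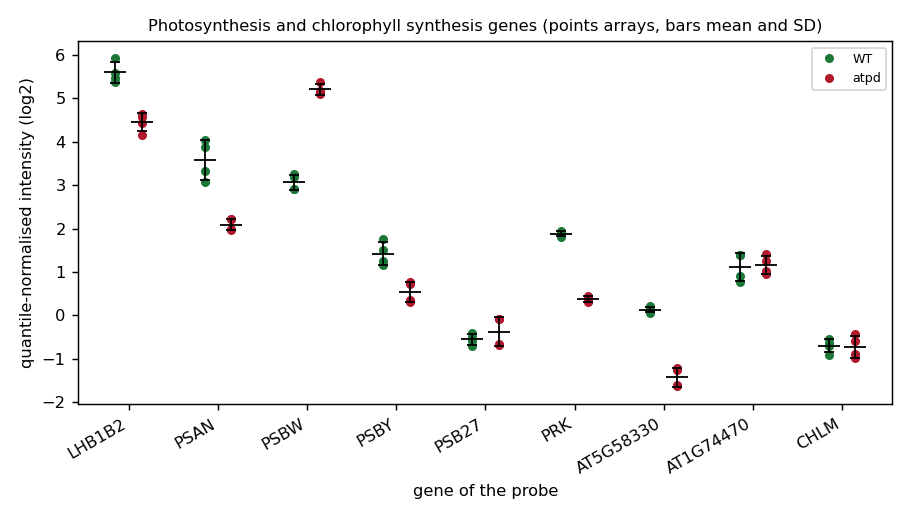
Quantile-normalised log2 intensity of genes of photosynthesis and chlorophyll synthesis, with a point per array (WT green, *atpd* red) and bars at the mean and SD of 4 arrays. LHB1B2, PSAN, PSBY, PRK and AT5G58330 lie lower in *atpd* and PSBW higher, while PSB27, AT1G74470 and CHLM overlap between genotypes.

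Of the 5 tested members of the plastid ribosomal protein list, 2 rose, 1 fell and 2 did not pass, with the same numbers adjusted over the list alone. AT3G54210 fell by 0.81 (SE 0.12, adjusted p = 0.000492), AT4G01310 rose by 0.60 (SE 0.14, adjusted p = 0.00712) and AT3G13120 rose by 1.58 (SE 0.58, adjusted p = 0.0477). The call of AT3G54210 was lost with the values as deposited (adjusted p = 0.400) and with pair means (0.0895). With array pairs as a random block, the adjusted p was 0.0967 for AT4G01310 and 0.224 for AT3G13120. The call of AT3G13120 was also lost with the replicate number as a block (adjusted p = 0.0547) and with an intensity trend and robust prior (0.0503). Pair means (0.121) and arrays 1 and 2 alone (0.0552) ended it too. So did leaving out *atpd* replicate 1 (0.0854), 2 (0.0865), 3 (0.0898) or 4 (0.0968) or WT replicate 3 (0.0826). Without WT replicate 4 its change was 0.92. In the antioxidant list, NTRC, a plastid thioredoxin reductase, rose by 0.58 (SE 0.18, adjusted p = 0.0245), and AT3G52960 differed by 0.39 (SE 0.42, adjusted p = 0.460). AT3G52960 was past the threshold as deposited (1.46, adjusted p = 0.0119) and in arrays 3 and 4 alone (1.12, adjusted p = 0.00350), but was at -0.33 in arrays 1 and 2 alone (adjusted p = 0.199). The NTRC call did not hold with the replicate block (adjusted p = 0.0591) or with array pairs as a random block (0.156), nor without WT replicate 3 (0.0550) or 4 (0.0571) or *atpd* replicate 1 (0.0555), 3 (0.0610) or 4 (0.0718).

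As groups, the 2 lists with at least 3 tested genes did not stand apart from the other probes. The camera set test placed 0 of them past the threshold, with unadjusted p of 0.416 for photosystem II and 0.544 for plastid ribosomal proteins and an adjusted p of 0.544 for each (adjusted p = 0.559 with an estimated correlation). The fry test, which does not compare a list with other genes, gave an adjusted p of 1.21e-05 for a shift upward on balance in photosystem II, where PSBW had the largest change, and 0.983 for the ribosomal list. This result turned with the scaling. With a common median both lists shifted downward (adjusted p = 0.0110 and 0.0342), and the ribosomal list shifted upward as deposited (5.90e-05) and after cyclic loess (0.0432) and downward with zeros at a floor (0.000164), with the 25th percentile filter (0.0407) and in arrays 3 and 4 alone (0.0476). For change in either direction fry gave adjusted p of 0.0102 and 1.28e-05, the latter 0.467 with pair means. The remaining lists had fewer than 3 tested genes each.

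Among probes named for a single gene, the 10 largest increases ranged from 6.20-fold to 14.8-fold, and 9 of the 10 had WT mean intensities below 1. AT2G21720 was 14.8-fold higher in *atpd* (log2 change 3.89, SE 0.75, adjusted p = 0.00250), and by 2.94 on the log2 scale without WT replicate 3, where its intensity was 0.00390. Its change was 2.57 in arrays 1 and 2 and 5.20 in arrays 3 and 4. The increase was 11.8-fold for AT4G19900 (3.56, SE 0.19, adjusted p = 5.32e-06) and 11.7-fold for AT1G16080 (3.54, SE 0.26, adjusted p = 1.74e-05). AT4G31530 was the brightest of them, with an intensity of 11.4 ± 1.07 in WT and 64.2 ± 2.52 in *atpd* (n = 4 in each). Its log2 change was 3.10 (adjusted p = 2.68e-06), but 1.33 with a common median. Quantile normalisation brought its 4 *atpd* values to nearly the same log2 level (SD 0.000226), so this limma p holds little of their deposited spread. AT4G32060, the MICU regulator of calcium uptake into mitochondria, rose by 2.77 and AT1G76450, a PsbP-family protein, by 2.66. The other increases were AT4G13680 (3.35), AT4G17070 (2.81), AT2G19870 (2.63, with 3 WT values) and AT1G44830, an AP2/ERF transcription factor (2.86, adjusted p = 0.0293). The call of AT1G44830 was lost with array pairs as a random block (adjusted p = 0.242), with the replicate block (0.0522) and without *atpd* replicate 1 (0.0576), 3 (0.0756) or 4 (0.0737). Without WT replicate 4, where it was at 0.00265, its change was 1.81. In arrays 1 and 2 alone the change of AT1G44830 was 1.08 (adjusted p = 0.0926) and in arrays 3 and 4 alone 4.63 (adjusted p = 0.0501).

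The 10 largest decreases ended at low intensities, with means of at most 0.186 in *atpd* and at most 0.486 in WT. AT5G17630, the XPT transporter that moves pentose phosphates across the plastid envelope, fell by 4.21 on the log2 scale (SE 0.27, adjusted p = 8.95e-06), from 0.305 ± 0.0411 to 0.0777 ± 0.00964 (n = 4 in each). On the deposited scale its log2 change was -1.97. AT4G02580, a subunit of mitochondrial complex I, fell by 3.55 (SE 0.44, adjusted p = 0.000220). AT5G19940, a plastoglobulin of the fibrillin family, fell by 2.76 (SE 0.20, adjusted p = 1.41e-05) and AT2G42490, a copper amine oxidase, by 2.61 (SE 0.26, adjusted p = 6.86e-05). With the values as deposited AT2G42490 was at -0.64 and its call was lost (adjusted p = 0.0557). AT1G29700 (-2.97), AT3G56250 (-2.84) and AT1G01500 (-2.65) were also lower. Calls of 3 others were lost as deposited (adjusted p = 0.0993 for AT5G05330, 0.0675 for AT2G27680 and 0.241 for AT2G41120) and in other settings. AT5G05330, an HMG-box protein, was at -4.22 (adjusted p = 0.0221, and 0.292 with array pairs as a random block). It was at 0.00214 on *atpd* replicate 2, without which the change was -2.81, and it was -5.21 without *atpd* replicate 1 and -4.83 without *atpd* replicate 3. AT2G27680, with 3 *atpd* values, was at -3.45 (0.00110 and 0.0506), and at -4.16 without *atpd* replicate 3. AT2G41120 was at -2.88 (adjusted p = 0.0232), with adjusted p of 0.107 for pair means and 0.0528 without WT replicate 2, 0.0612 without *atpd* replicate 3 and 0.0553 without *atpd* replicate 4. It was at -3.52 without *atpd* replicate 1 and -3.62 without *atpd* replicate 2. Its change was -1.44 in arrays 1 and 2 and -4.31 in arrays 3 and 4.

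The 20 genes, chosen for large changes on these same arrays, kept their direction in all 4 scalings. Their sizes did not: with the values as deposited the decreases ranged from -2.89 to -0.64 and 6 of the 10 passed the threshold, while the increases ranged from 2.50 to 5.17, the latter for AT2G21720, and all 10 passed. With a common median the decreases ranged from -4.06 to -1.81 and the increases from 1.33 to 4.01, and all 20 passed, as they did after cyclic loess.

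**Figure D2:**
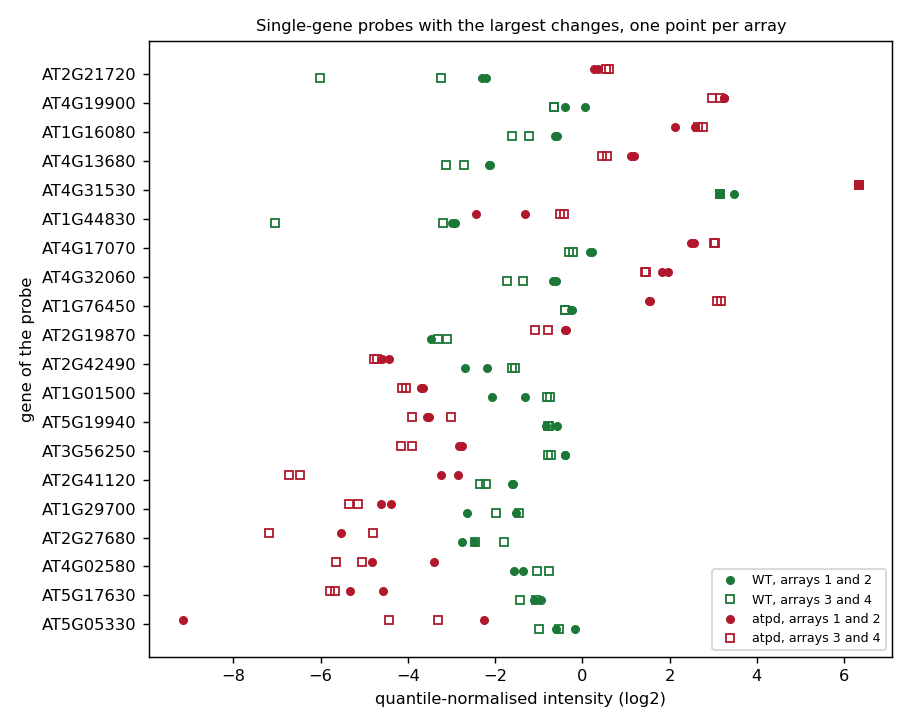
Quantile-normalised log2 intensity on each array for the single-gene probes with the 10 largest increases and the 10 largest decreases (WT green, *atpd* red, arrays 1 and 2 filled circles, arrays 3 and 4 open squares). The *atpd* values lie to the right of WT for the upper 10 genes and to the left for the lower 10, and the open and filled symbols of a genotype often sit apart.

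Over all 2921 tested probes, limma placed 1513 past an adjusted p of 0.05, of which 625 were higher and 888 lower in *atpd* (41.3% higher), and 1678 passed at an unadjusted p under 0.05. Among single-gene probes 142 were higher and 163 lower, of 583 tested. The arrays of a genotype fell into 2 pairs, replicates 1 and 2 and replicates 3 and 4. With these pairs as a random block 924 probes were called (336 higher, 588 lower), all of them among the 1513, and with pair means 686 (289 higher, 397 lower). Within replicates 1 and 2 alone 1603 probes were called and within replicates 3 and 4 alone 1710, and with the array set as a block 1813. In each set alone the error is only the spread within pairs, which may be repeats of the same RNA. Those counts are therefore no independent support for the 1513. Across probes the log2 change in the 2 sets correlated at r = 0.787 (probes are not independent replicates), and 79.9% of the tested probes had the same sign in both.

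The split between higher and lower calls depended on the scaling. With the values as deposited, 1829 probes were higher and 260 lower (87.6% higher), with the median of all log2 changes at 0.996, against -0.090 after quantile normalisation, -0.17 with a common median and 0.030 after cyclic loess. The deposited intensities of the genotypes differed in shape. The median above 0 was 0.279 to 0.303 on the WT arrays and 0.613 to 0.705 on the *atpd* arrays, and the log2 difference was 1.49 at the 10th percentile, 1.17 at the 50th and -0.34 at the 99th.

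**Figure D3:**
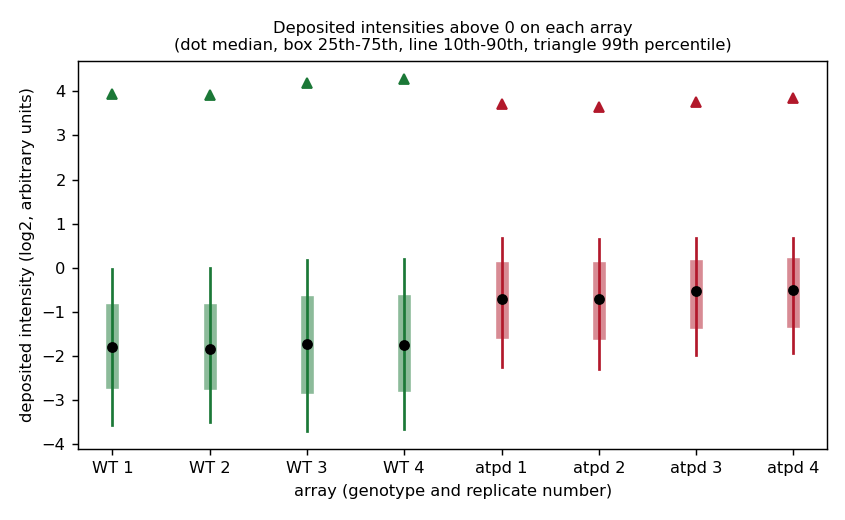
Distribution of the deposited intensities above 0 on each array, on a log2 axis in arbitrary units (dot median, box 25th to 75th percentile, line 10th to 90th, triangle 99th). The medians of the 4 *atpd* arrays lie above those of the 4 WT arrays, and their 99th percentiles lie below.

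**Figure D4:**
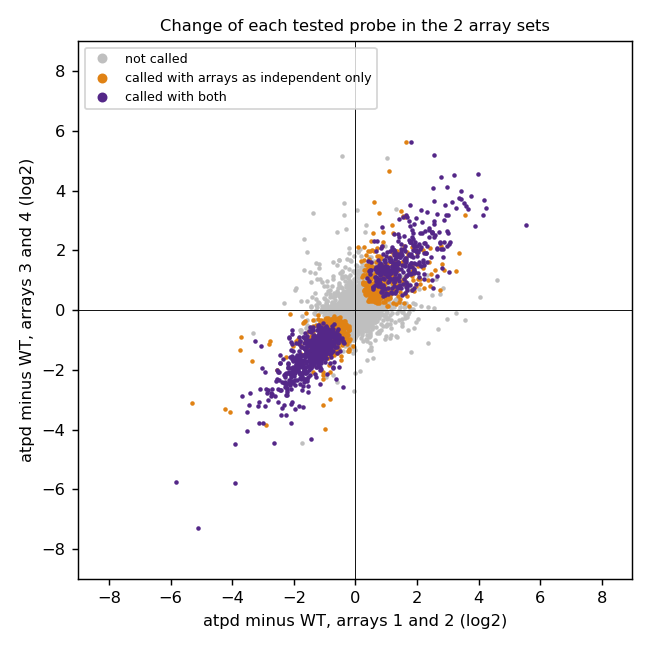
Log2 change of each tested probe in arrays 3 and 4 against that in arrays 1 and 2. Grey probes were not called, orange ones were called only with arrays treated as independent and purple ones, 924 probes, also with array pairs as a random block.

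A further 57 probes were above 0 on at least 3 *atpd* arrays and at most 1 WT array, and 22 the other way round. Of the first, 13 were named for a single gene. The median intensity was 0.571 in *atpd* for the 57 probes and 0.0280 in WT for the 22. The brightest single-gene probe was that of AT2G46300, at 1.64 ± 0.0361 in *atpd* (n = 4) and above 0 on 1 WT array, and it was picked after its values were seen. This probe has number 2667, and the LHB1B2 probe, at 62.3 in WT, has number 2665. Probes 2666 and 2669, also among the 57, lie near 2665 too. Probe 266, another of the 57, follows probe 265, at 100 on all 4 WT arrays. Probes 3500, 3501 and 3502 of the 57 follow probe 3499, likewise at 100 on all 4 WT arrays. Probes 813, 814 and 815 of the 57 lie near probe 811, at 100 on 2 WT arrays. Among the 22, probe 3214 precedes that of AT4G31530 (3215), at 64.2 in *atpd*, but probe 810 precedes probe 811, which was brighter in WT. These are examples, and such nearness was not counted over all of these probes. Whether such numbers adjoin on the array is not stated, and an effect of bright neighbours was not tested. A value at 0 need not mean that a transcript was absent.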

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

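Values of the named genes were searched for an array far from the other 3 of its genotype, and 3 of 64 groups of 4 arrays held one, against 3.2 from chance. AT4G31530 had a deposited intensity of 12.7 on WT replicate 2, where the other WT arrays lay between 10.1 and 11.6. Its normalised log2 value was 3.47 there, against 3.15 to 3.16, since quantile normalisation drew the other WT arrays together. The deposited values do not set this array far apart. AT1G44830 was at 0.00265 on WT replicate 4, against 0.0604 to 0.0803 on the other WT arrays. AT3G13120 was at 0.372 on *atpd* replicate 4, against 0.275 to 0.338. The gap was judged on the normalised log2 values.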

How the results depend on the processing

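The settings that use array pairs, array sets or column medians were chosen after the data were seen. The number of called probes moved by over 1.5 times in 2 settings: 924 with array pairs as a random block (336 higher, 588 lower) and 686 with pair means (289 higher, 397 lower). Fewer independent units enter both. With the values as deposited 1829 probes were higher and 260 lower, and the median change was 0.996. In the paired analysis with the replicate number as a block, 1656 probes were called (680 higher, 976 lower). That block ended the calls of AT1G44830, AT3G13120 and NTRC and of no other gene named by the fixed rule. Leaving out each array gave 1301 to 1499 calls (518 to 622 higher, 783 to 893 lower).

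The 20 largest changes never reversed: 507 of their values under alternatives kept direction and call and 18 lost the call. They were chosen from these same arrays by size, call and side of the WT mean. That choice left little room for a reversal, so its absence is no separate support. For the list members named above, 304 values kept direction and status (called or not), 28 lost the call, 3 gained it and 15 reversed. The reversals were in genes not past the threshold after quantile normalisation. PSB27 was at -0.058 with a common median and -0.13 in arrays 3 and 4 alone. AT1G74470 was at -0.90 with a common median, past the threshold (adjusted p = 0.0116), and -0.078 in arrays 1 and 2 alone, and ranged from -0.066 to 0.14 with an array left out. CHLM was at 1.01 as deposited, past the threshold (adjusted p = 0.000607), 0.060 after cyclic loess and 0.27 in arrays 1 and 2 alone, and ranged from -0.12 to 0.067 with an array left out. AT3G52960 was at -0.33 in arrays 1 and 2 alone. The calls gained with no change of direction were PSB27 as deposited (1.11) and AT3G52960 as deposited (1.46) and in arrays 3 and 4 alone (1.12). The mean shift of the photosystem II list against all genes was -0.34 as deposited and -0.34 with a common median (0.55 after quantile normalisation). The cause of these reversals was not tested. No list passed camera in any setting in which it was run. Camera takes no random block, and the robust prior and array weights do not enter it. The lists were therefore not run with array pairs as a random block, with the intensity trend and robust prior or with array weights. ATPD, with no probe of its own, gave no value in any setting. Background signal was not used here, so which low intensities lie within background is unknown.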

Other observations

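The lists in the first 2 paragraphs, and all tests below except the count of splits, were chosen after the data were seen. Of 15 tested pentatricopeptide repeat proteins, which process organelle RNA, 5 rose in *atpd* and 0 fell. Among all 583 tested single-gene probes 142 rose and 163 fell. As deposited 11 of the 15 rose and 0 fell, on a scale where 1829 of all 2921 tested probes rose and 260 fell. With a common median 4 of the 15 rose and 1 fell, and with the replicate block 5 rose and 1 fell. AT4G04370 rose by 2.63 on the log2 scale (SE 0.26, adjusted p = 7.73e-05), AT2G46050 by 2.13 (SE 0.19, adjusted p = 4.76e-05) and AT4G21170 by 1.48 (SE 0.19, adjusted p = 0.000241), and these 3 kept their call with array pairs as a random block. AT3G51320 (0.53) and AT1G79080 (0.51) did not (adjusted p = 0.124 and 0.0937). In a list of carbon fixation and sucrose synthesis 2 of 4 fell, PRK and AT5G58330, the chloroplast NADP-dependent malate dehydrogenase (-1.57, SE 0.15, adjusted p = 6.10e-05). Of 4 plastoglobulins 2 fell, AT5G19940 (-2.76) and AT2G46910 (-0.77, adjusted p = 0.00479, and 0.129 with pair means), the latter at 0.092 with the values as deposited.

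None of the 11 added lists stood apart from the other probes in camera. The lowest adjusted p was 0.346, shared by the pentatricopeptide repeat list and the carbon fixation list, whose unadjusted p were 0.0629 and 0.0546, and 0 lists passed at an unadjusted p under 0.05. By fry, which does not compare a list with other genes, the adjusted p were 0.000665 for a shift upward and 1.84e-05 for a shift downward, and 0.259 and 0.0366 with pair means. Single genes of other added lists changed as well. AGL54, a MADS-box gene, rose by 1.95 (SE 0.13, adjusted p = 9.60e-06), and AT-HF, an enzyme of histidine synthesis, by 1.17 (SE 0.14, adjusted p = 0.000166). In the list of AT-HF, AT2G44530 fell by 1.14 (SE 0.16, adjusted p = 0.000396), at -0.063 as deposited. SIRB (-0.65), CCS (-0.74), GLDH (-0.62) and LPA19 (-0.60) were also lower past the threshold. As deposited these 4 were at 0.41, 0.58, 0.55 and 0.51, below the median of 0.996 of all probes on that scale and past the threshold for CCS, GLDH and LPA19. All 4 lost their call with array pairs as a random block.

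Among the 50 brightest probes 9 were higher and 25 lower in *atpd*, but the balance moved with the scaling, to 4 and 41 with a common median and to 15 and 14 after cyclic loess. Probe 265, unnamed, was at the ceiling of 100 on all 4 WT arrays and at a mean of 22.9 in *atpd* (normalised log2 change -1.75, adjusted p = 0.00109), and its WT level is only a lower limit. Probe 3499 was also at 100 on all 4 WT arrays and was not called (-0.33, adjusted p = 0.0520). In the other direction, probe 1431, with several genes, reached the ceiling on 2 *atpd* arrays. Its mean was 10.3 in WT and 96.9 in *atpd* (3.53, adjusted p = 9.39e-07).

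The number of called probes was larger for the real genotypes than for any other split of the 8 arrays. Only 1 of the 35 splits, the real one, gave 1513 calls, and the highest other gave 2, so chance can be excluded only where the 8 arrays count as separate and unpaired samples. If both arrays of a pair hold the same RNA, the splits of the pairs are too few to exclude it. Among the 8 splits that part all 4 same-numbered pairs, the real one gave 1513 and the highest other 0, and 8 splits are too few for a share under 0.05. The position of probes on the array was set against this too. Probes were put in 12 columns by their number, an assumed layout, since the true layout is not given. These columns explained 1.14% of the variance of the changes (permutation p = 7e-04). After removal of their medians 1403 of the 1513 calls remained, so few calls depended on these columns. Other layouts and neighbouring probes were not tested, so position otherwise stays open. A difference in growth or handling between the genotypes stays open, since it would move with them.

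The deposited intensities differed in shape between genotypes. A single scaling factor per array would move all percentiles alike, yet the log2 difference at the 10th percentile exceeded that at the 99th by 1.83. A constant signal added on the *atpd* arrays after the zeros were set would leave few probes at 0 there. Yet 235 probes above 0 on at least 1 WT array were at 0 on all 4 *atpd* arrays, and 39 the other way round. Neither a single factor nor such a late constant accounts for the shape alone. A constant present before the zeros were set cannot be judged, since how they arose is not stated. Other technical sources and a true difference in the mutant's RNA stay open, and no biological explanation was tested.

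The pairing of arrays 1 and 2 and of arrays 3 and 4 may be a handling batch shared by both genotypes. The difference between the sets correlated across probes between WT and *atpd* at r = 0.361. The same RNA on both arrays of a pair would not by itself link WT with *atpd* in this way. Whether both arrays of a pair also measured the same RNA, beside a shared batch, cannot be told from these values. The correlation within pairs was 0.688, and 0.470 in WT and 0.856 in *atpd* taken alone, which separate plants of the same batch can give too. If pairs share RNA, the design has 2 samples per genotype, and the 686 calls from pair means are the nearest count obtained here. That fit took the pair means as unpaired and left out the set difference seen in both genotypes. Pair means were not fitted with the set as a block.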
